A study of Clostridium acetobutylicum ATCC 824 with 24 samples.

How the data were processed

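Transcript levels of Clostridium acetobutylicum ATCC 824, an anaerobic bacterium that ferments sugar to acids and then to solvents and that forms spores, were measured on 2-colour Agilent arrays of 60-base probes (60-mers). Each sample is a pair of RNA preparations of the same culture hour hybridised together. There are 24 samples: 6 comparisons among 5 strains (wild type and mutants in spo0A, sigF, sigE and sigG) at 4 hours each. Cultures grew at 37 °C in fermentors with a 10% inoculum and glucose kept above 200 mM. Mutants grew with 5 µg/ml of the antibiotic thiamphenicol and only wild-type colonies were heat-shocked before use, so wild type and mutants also differ in these treatments. Equal hours of different strains may be different stages of growth.

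The scanner files hold, per the file headers, intensity values from Agilent Feature Extraction 9.5.1.1: the mean brightness of each spot and the median of its local background in the Cy3 and Cy5 channels, not normalized, with Agilent's processed signals beside them. A further table, deposited by the authors, holds a log2 ratio per spot and sample. The steps behind it are not given in the sources used here. Over gene spots its columns correlated with the ratios of Agilent's processed signals, averaged over both arrays and turned to the order of strains in each title, with r from 0.815 to 0.981, slopes from 0.576 to 0.922 and medians from -0.04 to 0.02. Its direction is thus that of the titles and its values are compressed against Agilent's processed signals.

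Each sample had 2 arrays with the dyes exchanged. The labels list both dye orders for every sample, and the order of each array was read from the name of its scanner file. Ratios are the strain whose lesion acts later over the strain whose lesion acts earlier. Background was corrected by normexp with an offset of 50, log2 ratios were normalized within arrays by loess with control spots at weight 0, and outlier-flagged spots (0.676% of gene spots) were left out. Spots of a 60-mer were averaged. A gene's value is the median over its 60-mers, of which 3912 of 3916 genes have 2, so that it equals their mean. In the 6 comparisons, values of both 60-mers correlated across genes with r from 0.944 to 0.961, and 1 to 29 genes past the test had 60-mers of opposite sign and 9 to 58 had 60-mers over 2-fold apart. Both arrays of a sample were averaged and counted as 1 replicate. They correlated across genes with r from 0.684 to 0.983 (median 0.947). The range was 0.684 to 0.902 in sigE over sigF, and r was at least 0.872 in every other comparison.

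The number of arrays and the signal over background limit the precision: per array and channel, 8.66% to 93.9% of gene spots were well above background. Median net brightness was 211 (Cy3) and 247 (Cy5) for gene spots, and 32.8 and 22.6 for negative control spots. A gene was kept when at least 50% of its spots were well above background in either channel on at least 4 of 48 arrays, which kept 3809 genes and left out 107. Where a named gene was well above background in 1 strain's RNA only, an "at least" fold is given: the level of the bright strain against, per array, the higher of the dim strain's level and the lowest level of any 60-mer well above background, after loess and Aquantile normalization. No fold is given where this is not above 1 or both strains are dim.

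Tests used limma 3.58.1 and statmod 1.5.0 in R 4.3.3, and tables were handled with version 1.17.8 of its data.table package. A single linear model was fitted to all 24 samples with a coefficient per comparison (the mean log2 ratio over its 4 hours). The two-sided moderated p-values were adjusted by Benjamini-Hochberg over the 3809 genes, with a threshold of 0.05. Replicates are hours, and nothing in the labels says that they came from separate cultures, so p measures how steady a difference was over the hours and not the spread between cultures. The difference between both comparisons against spo0A and that between both against sigF were tested as contrasts of the same model. Lists were tested with camera at a preset correlation of 0.01, adjusted over 12 lists and 6 comparisons (for the differences, over their own tests). Of 72 list tests 29 passed, 15 as higher and 14 as lower, and 0 passed with an estimated correlation. fry, which tests whether a list's genes move on balance 1 way, passed 35, and its mixed form, which tests for change in either direction, passed 33.

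On simulated data, a log2 change of 1 was recovered in 82.1% (sigE over spo0A) to 95.5% (sigF over spo0A) of genes, and a change of 0.5 in 47.8% (sigE over spo0A) to 64.2% (WT over sigG). Unchanged genes among those called ran from 6 of 166 (sigG over sigF) to 12 of 165 (sigE over spo0A), and were 22 of 295 for the difference over spo0A, so that false calls exceeded 5% in places, and 2 of 100 unshifted lists had a camera p under 0.05.

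The files give locus tags without gene symbols or products. The pairs of tag and symbol and the gene lists come from general knowledge of the published annotation of this strain and were, with the tests and the alternatives not named otherwise, fixed before the data were examined. The 12 lists are sporulation regulators, engulfment and mother-cell genes, forespore genes, small acid-soluble spore proteins, solventogenesis, acid formation, butyryl-CoA formation, flagella and chemotaxis (runs of neighbouring tags), granulose and glycogen, heat shock, ATP synthase, and the megaplasmid pSOL1 (tags beginning CAP), since cells that lost it are the other cell type such cultures could hold. A further 5 planned lists needed product names and were not formed. The rule for named genes took, per comparison, the 4 targeted genes, the 8 largest and 8 smallest mean log2 ratios among genes past the test with the same sign in all 4 hours, and of each list up to 2 of the largest and 2 of the smallest past the test, or else the member largest in size. For the differences it took the 5 largest and 5 smallest. Without an annotation this was limited, after the data were seen, to tags paired with a symbol and to spore protein tags. Unlisted tags are given without function. The text gives a part of the genes this rule took.

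The arrays lie on 13 slides scanned in 4 runs. The first run holds 15 of the 16 arrays of both comparisons against spo0A, and the second all 16 of both against sigF. Alternatives were no background subtraction, Agilent's processed signals, median centring, scaling between arrays, the authors' values, no gene filter, a stricter filter (2927 genes), each comparison fitted alone, a variance trend with robust estimation, all 48 arrays with a dye term and sample or slide as a random block, a 2-fold threshold, hour as a replicate block for the differences, and each hour left out in turn. Alternatives chosen after seeing the data were the median over all spots, a dye term per scan run, leaving out the slide that 2 comparisons share, and leaving out 5 samples with a dim array (under 30% of gene spots well above background in both channels). Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.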

Results

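The series followed the sporulation programme of Clostridium acetobutylicum through mutants blocked at successive regulators. Spo0A is the response regulator that starts sporulation, SigF the early sigma factor of the forespore, SigE that of the mother cell, and SigG the later one of the forespore. Each comparison set a strain that gets further in this order against one that stops earlier, to find the genes that depend on the factor in between. The hours were those at which that factor was thought to be active. There were 6 comparisons with 4 samples each: sigF over spo0A and sigE over spo0A mutants at 14, 16, 20 and 22 h, sigE over sigF and sigG over sigF mutants at 22, 24, 26 and 28 h, sigG over sigE mutants at 24, 26, 30 and 32 h, and wild type (WT) over sigG mutant at 28, 30, 34 and 36 h. Every sample was measured on 2 dye-swapped arrays. The share of gene spots well above background, per array and channel, ran from 36.8% to 86.8% in sigF over spo0A, 26.1% to 89.5% in sigE over spo0A and 13.3% to 93.7% in sigE over sigF. It ran from 19.6% to 92.8% in sigG over sigF, 16.4% to 93.9% in sigG over sigE and 8.66% to 85.9% in WT over sigG. Values below are mean log2 ratios ± SD over the 4 hours (n = 4), and adjusted p values of genes are limma's.

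The transcripts of the targeted genes came first. The spo0A transcript (CAC2071) was 3.14-fold higher in the sigF mutant than in the spo0A mutant (1.65 ± 0.33, adjusted p = 6.7e-08) and 2.91-fold higher in the samples labelled sigE mutant (1.54 ± 0.39, adjusted p = 1.3e-07), in 4 of 4 hours each. The sigF transcript (CAC2306) was 5.25-fold higher in the sigG mutant than in the sigF mutant (2.39 ± 0.79, adjusted p = 3.89e-08), where 1 of 8 arrays measured it well above background in sigF mutant RNA. In sigF over spo0A it stood at -0.56 ± 0.16 (adjusted p = 0.0674) and passed with Agilent's processed signals (-1.42, adjusted p = 0.00083) and the authors' values (-0.85, adjusted p = 0.0172). Between the samples labelled sigE mutant and the sigF mutant it did not pass the test (0.29 ± 0.22, adjusted p = 0.372). The sigG transcript (CAC1696) was 9.45-fold higher in wild type than in the sigG mutant (3.24 ± 0.74, adjusted p = 3.18e-10), whose RNA showed it well above background on 2 of 8 arrays. It was also lower in the sigG mutant than in the samples labelled sigE mutant (-1.72 ± 0.32, adjusted p = 3.24e-06). It was higher in the sigG mutant than in the sigF mutant (0.82 ± 0.19, adjusted p = 0.00176), a call lost with scaling between arrays (0.49, adjusted p = 0.477).

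The sigE transcript (CAC1695) went against the label. It was higher in the samples labelled sigE mutant than in the spo0A mutant (2.05 ± 0.63, adjusted p = 1.91e-08), than in the sigF mutant (1.37 ± 0.28, adjusted p = 1.97e-05) and than in the sigG mutant (-0.92 ± 0.25 in sigG over sigE, adjusted p = 0.00056), in 4 of 4 hours each. In spo0A mutant RNA 1 of 8 arrays showed it well above background, in sigF mutant RNA 3 of 8. The positions of the 60-base probes (60-mers) relative to the disrupted part of each gene are not given in the sources used here, and a 60-mer outside that part checks nothing. RNA of this strain is therefore called "labelled sigE mutant". In sigF over spo0A the sigE and sigG transcripts were not well above background on any of the 8 arrays in either strain, so no fold is given.

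**Figure D1:**
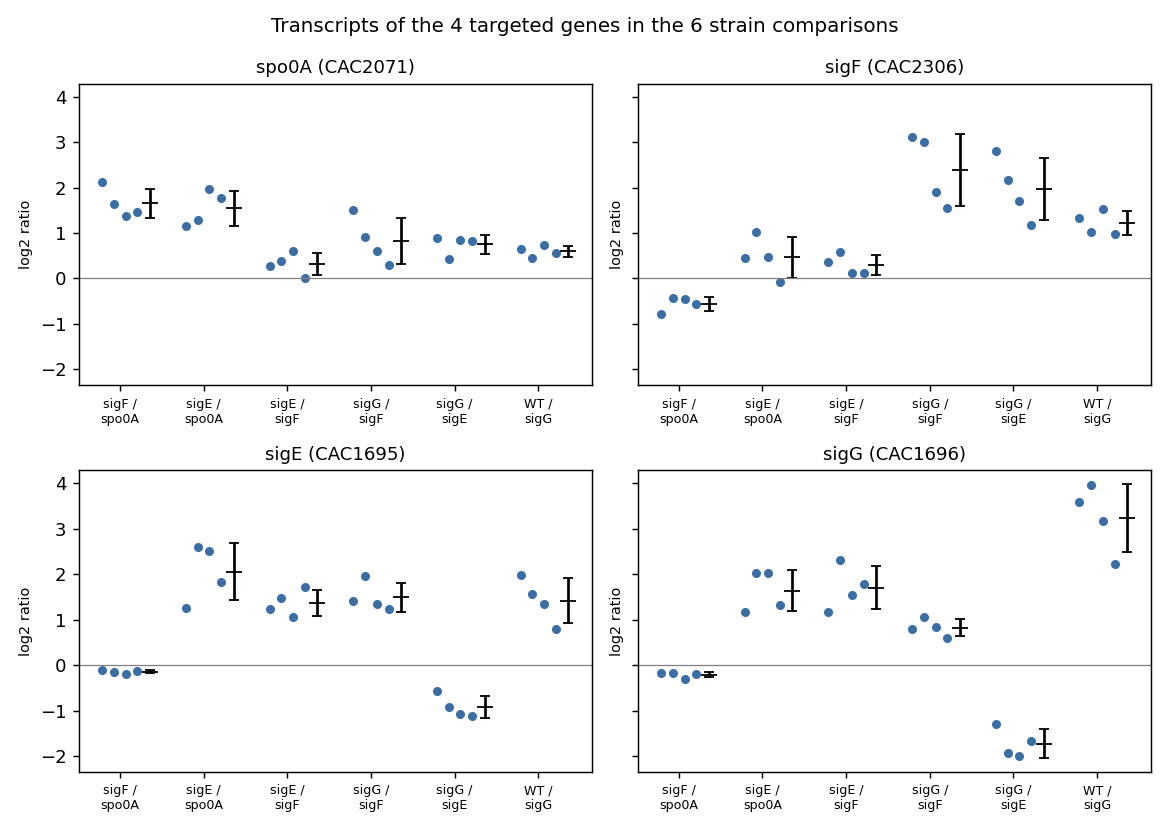
Log2 ratios (vertical axis) of the spo0A, sigF, sigE and sigG transcripts in the 6 strain comparisons (horizontal axis). Points are the 4 hours in order and the bar is the mean ± SD; the sigE transcript lies above 0 in sigE over spo0A (mean 2.05) and sigE over sigF (mean 1.37).

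The sigF mutant against the spo0A mutant asked which genes need Spo0A. Genes of solvent formation were higher in the sigF mutant. ctfB (CAP0164) and ctfA (CAP0163), subunits of the CoA transferase of acetone formation, stood at 4.82 ± 0.57 (28.3-fold, adjusted p = 2.51e-08) and 3.54 ± 0.72 (adjusted p = 8.59e-07). The aldehyde-alcohol dehydrogenase gene adhE1 (CAP0162) stood at 4.03 ± 0.67 (adjusted p = 3.56e-07), the butanol dehydrogenase gene bdhB (CAC3298) at 3.88 ± 0.49 (adjusted p = 6.68e-10) and the acetoacetate decarboxylase gene adc (CAP0165) at 2.80 ± 0.53 (adjusted p = 2.89e-08). Of 7 solventogenesis genes 6 rose and 1 did not pass (7 rose adjusted over the list alone), with a camera adjusted p = 2.48e-06 (0.201 with an estimated correlation). The gene that did not pass over all genes was adhE2 (CAP0035, 0.97 ± 1.00, adjusted p = 0.0602), another aldehyde-alcohol dehydrogenase. abrB (CAC0310), a transition-state regulator, rose 8.22-fold (3.04 ± 0.63, adjusted p = 3.45e-09).

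Few genes of later sporulation passed in sigF over spo0A. Among 11 sporulation regulators 2 rose, spo0A and abrB, and 1 fell, also adjusted over the list alone (camera adjusted p = 0.924). spoVD (CAC2130), a penicillin-binding protein of the spore cortex, was the only 1 of 12 engulfment and mother-cell genes to pass, by both adjustments, and fell (-0.77 ± 0.55, adjusted p = 0.00481). None of 3 forespore genes and none of 8 heat shock genes passed by either adjustment, but groEL (CAC2703, -0.86, adjusted p = 0.0604) passed as lower with Agilent's processed signals (-0.94, adjusted p = 0.00644), median centring (-1.09, adjusted p = 0.00433) and the authors' values (-0.82, adjusted p = 0.035), and without 22 h. The heat shock median was -0.20 at 14 h, 0.05 at 16 h, 0.55 at 20 h and 1.25 at 22 h. Of 50 flagella and chemotaxis genes 18 fell and 1 rose (20 and 2 adjusted over the list alone), with a median of -0.32 (-0.50 with Agilent's processed signals) and a camera adjusted p = 0.00167 (0.704 with an estimated correlation). On the megaplasmid pSOL1, 55 of 177 genes rose and 12 fell, also over the list alone, with a median of 0.14 (0.30 with Agilent's processed signals, 0.25 with the authors' values) and a camera adjusted p = 0.00533 (0.605 with an estimated correlation). The unlisted tags CAC0079 (8.86 ± 0.69, adjusted p = 3.64e-15) and CAC0078 (6.22 ± 1.93, adjusted p = 1.79e-09) rose most, and were well above background in spo0A mutant RNA on 3 and 2 of 8 arrays. CAC2585 and CAC1862 fell, and were well above background in sigF mutant RNA on 1 and 3 of 8 arrays. limma called 1427 of 3809 genes, 826 higher and 601 lower, 435 of them at least 2-fold. The count was 810 with this comparison fitted alone and 2254 with slide as a random block, which counts dye-swapped arrays as separate samples.

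The samples labelled sigE mutant against the spo0A mutant addressed the same regulon. Solvent genes were again higher, with 1 opposite member. bdhB stood at 3.58 ± 0.33 (11.9-fold, adjusted p = 1.46e-09), adc at 3.54 ± 0.58 (adjusted p = 7.84e-10), ctfB at 3.10 ± 1.12 (adjusted p = 5.58e-06) and adhE1 at 3.02 ± 0.57 (adjusted p = 1.13e-05). adhE2 was 9.73-fold lower (-3.28 ± 1.60, adjusted p = 1.09e-06), with -1.27 at 14 h and -5.05 at 22 h. The list thus had 6 members up and 1 down, also adjusted over the list alone (camera adjusted p = 0.00237, and 0.47 with an estimated correlation). abrB rose 3.26-fold (1.71 ± 0.49, adjusted p = 5.35e-06).

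All 8 ATP synthase genes fell in sigE over spo0A, also adjusted over the list alone, with a median of -1.45 (-0.93 with median centring) and a camera adjusted p = 0.0038 (0.605 with an estimated correlation). atpG (CAC2866) fell most (-2.20 ± 1.16, adjusted p = 4.04e-05), while the calls of atpD, atpC, atpE and atpA were lost with scaling between arrays, where atpD stood at -1.69 (adjusted p = 0.103). Over the alternatives 2 to 8 of the 8 ATP synthase genes fell. The fall was not steady over the hours: the list's median was -0.42 at 14 h, -0.82 at 16 h, -2.06 at 20 h and -2.46 at 22 h. Of 7 genes of butyryl-CoA formation, the trunk shared by acid and solvent pathways, 4 fell and 3 did not pass (5 fell adjusted over the list alone; camera adjusted p = 0.0284, and 0.605 with an estimated correlation), 1 to 5 fell over the alternatives, and the median of -0.71 became -0.14 with median centring. By hour the butyryl-CoA median was 0.06 at 14 h, -0.17 at 16 h, -1.23 at 20 h and -1.59 at 22 h. The thiolase gene thlB (CAP0078) stood at -2.10 ± 0.66 (adjusted p = 2.11e-07). Among acid formation genes 2 of 5 rose, also over the list alone, led by the acetate kinase gene ack (CAC1743, 0.78 ± 0.28, adjusted p = 9.04e-05; camera adjusted p = 0.293).

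Of 11 sporulation regulators 6 rose and 5 did not pass in sigE over spo0A, also adjusted over the list alone (camera adjusted p = 0.0226, and 0.58 with an estimated correlation), among them sigG (1.64 ± 0.45, adjusted p = 2.01e-06). Later sporulation genes did not follow: 1 of 12 engulfment and mother-cell genes passed and fell (0 over the list alone), as did 1 of 3 forespore genes and 2 of 5 genes of small acid-soluble spore proteins, the latter counts also over the list alone. The spore protein gene CAC1522 stood at -0.73 ± 0.40 (adjusted p = 0.00303). The unlisted tags CAC2944 (5.97 ± 1.56, adjusted p = 6.47e-10) and CAC2293 (5.94 ± 1.41, adjusted p = 2.79e-10) rose most, and CAC3055 (-4.61 ± 0.44, adjusted p = 1.25e-11) fell most. limma called 1832 genes, 958 higher and 874 lower, 625 at least 2-fold, and 1182 with the comparison fitted alone.

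The difference between both comparisons against spo0A was tested at their shared hours. thlB (-2.71, adjusted p = 1.51e-05) and adhE2 (-4.25, adjusted p = 6.43e-05) were lower in the samples labelled sigE mutant than in the sigF mutant by this route, in 4 of 4 hours each, as the rule for naming them required. The call of adhE2 was lost with scaling between arrays (-4.14, adjusted p = 0.0824). sigE and sigG were called higher, but with both near background in sigF over spo0A no size is given here. Of 50 flagella and chemotaxis genes 13 were higher and 0 lower (16 and 0 adjusted over the list alone; camera adjusted p = 2.95e-07, and 0.504 with an estimated correlation). limma called 662 genes, 290 higher and 372 lower. That count was 111 when the difference was fitted on its own 8 samples, 1161 without 14 h, 209 without 16 h, 281 without 20 h, 368 without 22 h and 1825 with slide as a random block, and median centring moved the share of higher calls from 43.8% to 75.8%. With hour as a replicate block it was lowest, at 17, though the hours were not shown to pair the samples.

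Both comparisons against spo0A shared many calls: 520 genes were higher in both and 411 lower in both, where independent lists of these sizes would share 207.7 and 137.9. Simulated unchanged strains that share the spo0A RNA gave 0, which sets no bound, since unchanged strains give almost no calls. With hours split so that no spo0A sample was shared, 412 or 253 genes were higher in both and 343 or 198 lower in both, and with each comparison fitted alone 274 were higher in both. Both ratios are taken over the spo0A mutant, so a peculiarity of that strain or its culture enters both, also with the hours split. An excess over independent lists is therefore no independent evidence of shared regulation. Across genes, which are not independent replicates, the log2 ratios had r = 0.686 and a covariance of 0.525. The simulated unchanged strains gave r = 0.498 and a covariance of 0.0209. Their r follows from the shared RNA assumed in the simulation and is no yardstick for strains with many changed genes. With the hours split, the observed r was 0.613 or 0.592.

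The samples labelled sigE mutant against the sigF mutant asked which genes need SigF. adhE2 was 30.5-fold lower in the samples labelled sigE mutant (-4.93 ± 0.63, adjusted p = 8.16e-08), ctfB 4.42-fold lower (-2.15 ± 0.74, adjusted p = 0.00111) and the crotonase gene crt (CAC2712) 4.07-fold lower (-2.02 ± 0.23, adjusted p = 5.38e-06). All 7 butyryl-CoA genes fell, also adjusted over the list alone, with a median of -1.18 and a camera adjusted p = 2.48e-06 (0.379 with an estimated correlation). Over 5 alternative ways of processing 2 to 7 of them fell, and the median was -0.74 with median centring and -1.96 with scaling between arrays. Of 7 solventogenesis genes 4 fell and 1 rose (5 and 2 adjusted over the list alone), with a median of -1.63 (-1.01 with median centring, -2.97 with scaling between arrays) and a camera adjusted p = 0.0289 (0.605 with an estimated correlation). In this list adhE1 (-1.76 ± 0.65, adjusted p = 0.00653) and ctfA (-1.63 ± 0.42, adjusted p = 0.00721) lost their calls without the 24 h sample (adjusted p = 0.0506 and 0.0522). The chaperonin genes groEL (2.45 ± 0.77, adjusted p = 4.25e-05) and groES (CAC2704, 1.94 ± 0.67, adjusted p = 0.000904) rose, the only 2 of 8 heat shock genes to pass by either adjustment (camera adjusted p = 0.417).

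Later sporulation genes did not rise in sigE over sigF. sigE and sigG (1.71 ± 0.48, adjusted p = 7.01e-06) were the only 2 of 11 sporulation regulators to pass, by both adjustments. None of 12 engulfment and mother-cell genes, of 5 genes of small acid-soluble spore proteins, of 5 granulose genes or of 8 ATP synthase genes passed by either adjustment. The ATP synthase median changed sign, from -1.97 at 22 h and -0.84 at 24 h to 0.37 at 26 h and 0.76 at 28 h. A mean over the hours does not describe that list. Of 50 flagella and chemotaxis genes 12 rose and 1 fell, also over the list alone (camera adjusted p = 0.00221, and 0.704 with an estimated correlation). ack rose 2.24-fold (1.16 ± 0.41, adjusted p = 5.05e-06), in an acid formation list with 2 of 5 higher and 2 lower by both adjustments. Both lower calls were lost with median centring, and 0 to 2 genes of the list fell over the alternatives. The unlisted tags CAC0079 (-6.91 ± 0.93, adjusted p = 5.04e-13) and CAC0941 (4.50 ± 1.21, adjusted p = 0.000694) moved most in either direction. In RNA labelled sigE mutant CAC0079 was well above background on 3 of 8 arrays. Dye-swapped arrays reached their lowest correlation across genes in this comparison, with r from 0.684 at 26 h to 0.902 at 28 h. limma called 912 genes, 551 higher and 361 lower, 251 at least 2-fold. The count was 397 without the 24 h sample, 516 with median centring, which moved the share of higher calls from 60.4% to 81.4%, 2197 with slide as a random block, and 155 without samples that had a dim array, here those of 24 and 26 h.

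The sigG mutant against the sigF mutant addressed the same regulon and gave the largest count. Solvent genes, though not all of them, were far lower in the sigG mutant. adhE2 was 100.1-fold lower (-6.65 ± 0.32, adjusted p = 8.67e-11), ctfB 41.3-fold (-5.37 ± 0.59, adjusted p = 3.16e-09) and adhE1 31.5-fold (-4.98 ± 0.54, adjusted p = 1.21e-08). Heat shock genes were lower too: hsp18 (CAC3714), a small heat shock protein, 30.2-fold (-4.92 ± 0.69, adjusted p = 2.09e-06), clpC (CAC3189), a protease ATPase, 25.6-fold (-4.68 ± 0.70, adjusted p = 2.69e-08) and dnaK (CAC1282), a chaperone, 13.7-fold (-3.77 ± 0.92, adjusted p = 8.22e-09). The operon of sigF rose, with spoIIAB (CAC2307), whose product holds SigF inactive, 9.92-fold higher (3.31 ± 0.72, adjusted p = 2.16e-09) and spoIIAA (CAC2308), its antagonist, at least 3.22-fold higher, being well above background on none of 8 arrays in sigF mutant RNA.

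By list, 5 of 7 solventogenesis genes fell in sigG over sigF and 0 rose, also adjusted over the list alone (median -4.98, which was -3.59 with median centring and -3.02 with scaling; camera adjusted p = 0.00533, and 0.492 with an estimated correlation). The other 2 did not pass, and the list's mean of -3.41 was smaller in size than its median. Of 8 heat shock genes 6 fell and 1 rose (6 and 2 over the list alone), with a median of -3.64 (-2.36 with median centring, -2.20 with scaling between arrays) and a camera adjusted p = 0.0108 (0.605 with an estimated correlation). Over the alternatives 0 to 2 of them rose. Sporulation regulators rose in 9 of 11 cases, also over the list alone (median 1.17, which was 2.04 with Agilent's processed signals, 1.86 with median centring and 0.73 with scaling; camera adjusted p = 0.000921, and 0.413 with an estimated correlation), and all 5 granulose genes, which make and use the storage polymer granulose, rose by both adjustments (median 1.25, which was 2.85 with Agilent's processed signals and 0.76 with scaling; camera adjusted p = 0.0038, and 0.522 with an estimated correlation). The granulose gene glgC (CAC2237) stood at 1.81 ± 0.35 (adjusted p = 1.44e-07). Flagella and chemotaxis genes fell in 33 of 50 cases and rose in 4, also over the list alone, with a camera adjusted p = 2.48e-06 (0.605 with an estimated correlation) and a median of -0.68 that turned to 0.06 with median centring, and 15 to 33 fell over the alternatives. Butyryl-CoA genes fell in 5 of 7 cases (6 over the list alone; camera adjusted p = 0.0239, and 0.605 with an estimated correlation), with a median of -0.78 that turned to 0.47 with median centring, and 1 to 5 fell over the alternatives. Forespore genes fell, 3 of 3 by both adjustments (camera adjusted p = 0.128), among them the protease gene spoIVB (CAC2072, -0.77 ± 0.14, adjusted p = 3.23e-07), and CAC1522 fell 2.44-fold. On pSOL1 74 of 177 genes rose and 52 fell (75 and 52 over the list alone; camera adjusted p = 0.254). The unlisted tags CAC0663 (5.55 ± 0.62, adjusted p = 3.78e-12) and CAC0587 (-5.26 ± 0.51, adjusted p = 5.43e-08) moved most. In sigF mutant RNA CAC0663 was well above background on 2 of 8 arrays. limma called 2413 genes, 1176 higher and 1237 lower, 784 at least 2-fold. Agilent's processed signals moved the median of all genes from -0.01 to 0.14 and the share of higher calls from 48.7% to 58.2%, and with median centring 1776 of these calls kept their direction and 92 were called in the opposite one.

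The difference between both comparisons against sigF was tested at their shared hours. Relative to the samples labelled sigE mutant, the sigG mutant was higher in spoIIAB (2.83, adjusted p = 1.41e-05) and sigF (2.10, adjusted p = 0.000118). The value of sigF is uncertain in size, since it was near background in sigF mutant RNA in sigG over sigF. spoIIGA (CAC1694), the first gene of the operon that holds sigE, was called higher, but no size is given here, since it was well above background on none of 8 arrays in sigF mutant RNA and none of 8 in RNA labelled sigE mutant. The sigG mutant was lower in clpC (-4.58, adjusted p = 2.9e-05), dnaK (-3.67, adjusted p = 1.18e-05) and grpE (CAC1281, -3.28, adjusted p = 0.000147), in 4 of 4 hours each, as the rule for naming them required. Heat shock genes were lower in 7 of 8 cases, also adjusted over the list alone (camera adjusted p = 4.91e-05, and 0.398 with an estimated correlation). Flagella and chemotaxis genes were lower in 40 of 50 cases (41 over the list alone; camera adjusted p = 1.56e-14, and 0.398 with an estimated correlation). limma called 1552 genes, 712 higher and 840 lower. The count was 967 without 26 h, 815 with scaling between arrays, 735 without samples that had a dim array and 2576 with slide as a random block, and Agilent's processed signals moved the share of higher calls from 45.9% to 56.3%.

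Over the sigF mutant, 360 genes were higher and 268 lower in both the samples labelled sigE mutant and the sigG mutant, where independent lists would share 170.1 and 117.2. Simulated unchanged strains gave 0, which again sets no bound. With hours split so that no sigF sample was shared, 171 or 137 genes were higher in both and 98 or 57 lower in both. A peculiarity of the sigF mutant or its culture enters both ratios here too, so the excess is no independent evidence of shared regulation. Across genes the log2 ratios had r = 0.551 and a covariance of 0.319. The simulated unchanged strains gave r = 0.499 and a covariance of 0.0209. Their r follows from the shared RNA assumed in the simulation and is no yardstick for strains with many changed genes. With the hours split, the observed r was 0.351 or 0.635.

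The sigG mutant against the samples labelled sigE mutant asked which genes need SigE. All 8 heat shock genes fell, also adjusted over the list alone, with a median of -2.72 and a camera adjusted p = 1.63e-05 (0.421 with an estimated correlation). dnaK fell 10.3-fold (-3.37 ± 0.96, adjusted p = 2.14e-07), clpC 11.2-fold (-3.49 ± 1.53, adjusted p = 6.63e-06) and hsp18 12.4-fold (-3.63 ± 1.84, adjusted p = 0.00023). The list's median was -3.69 at 24 h, -3.44 at 26 h, -2.38 at 30 h and -1.13 at 32 h. Genes of the sigF operon rose, with spoIIAB at 2.61 ± 0.60 (adjusted p = 2.51e-07) and sigF at 1.97 ± 0.69 (adjusted p = 2.84e-06), and spoIIGA rose at least 2.36-fold (adjusted p = 4.46e-07). Sporulation regulators rose in 7 of 11 cases and fell in 2, sigE and sigG, by both adjustments (camera adjusted p = 0.0162, and 0.545 with an estimated correlation).

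Granulose genes rose in sigG over sigE, 5 of 5 by both adjustments (median 0.85, which was 1.87 with Agilent's processed signals; camera adjusted p = 0.00198, and 0.489 with an estimated correlation), with glgC at 1.54 ± 0.75 (adjusted p = 6.63e-06). Of 50 flagella and chemotaxis genes 39 fell (40 adjusted over the list alone, with 1 rise, and 14 to 39 over 5 alternative ways of processing; median -0.76, camera adjusted p = 8.66e-10, and 0.489 with an estimated correlation). Solventogenesis genes fell in 4 of 7 cases and rose in 1, also over the list alone (camera adjusted p = 0.0471, and 0.605 with an estimated correlation), with ctfA at -2.78 ± 0.90 (adjusted p = 3.82e-05). Over the alternatives 2 to 4 of them fell and 0 to 1 rose. The list's median of -1.99 became -1.22 with median centring, and ctfB and adhE1 lost their calls with scaling between arrays. On pSOL1 60 of 177 genes rose and 31 fell (62 and 32 over the list alone; camera adjusted p = 0.0279, and 0.619 with an estimated correlation), with a median of 0.13 that was -0.0029 with median centring and 0.34 with Agilent's processed signals. None of 12 engulfment and mother-cell genes passed by either adjustment. Genes of small acid-soluble spore proteins fell in 4 of 5 cases by both adjustments (camera adjusted p = 0.0866), and in 2 to 4 over the alternatives. Of these CAC1522 (-0.68 ± 0.71, adjusted p = 0.00621) lost its call without the 26 h sample (adjusted p = 0.12). CAC2365 lost its call without that sample too (adjusted p = 0.197), with median centring (adjusted p = 0.131) and with scaling between arrays (adjusted p = 0.201). CAC0079 (8.36 ± 0.61, adjusted p = 1.15e-14) and CAC3190 (-3.32 ± 1.60, adjusted p = 1.66e-05) moved most among unlisted tags. In RNA labelled sigE mutant CAC0079 was well above background on 3 of 8 arrays. limma called 1761 genes, 837 higher and 924 lower, 355 at least 2-fold. The count was 977 without the 26 h sample, 637 with the comparison fitted alone and 2653 with slide as a random block.

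Wild type against the sigG mutant asked which genes need SigG, between strains that also differed in antibiotic and in heat-shocking of the starting colonies. Genes of the late programme were higher in wild type. The spore protein gene CAC2365 stood at 4.50 ± 0.97 (adjusted p = 6.82e-12; 3.27 and 5.73 by 60-mer), and the regulator genes spoVT (CAC3214) of the forespore at 2.93 ± 0.49 (adjusted p = 8.52e-13; 4.05 and 1.82 by 60-mer) and spoIIID (CAC2859) of the mother cell at 2.73 ± 1.02 (6.62-fold, adjusted p = 2.46e-09). In sigG mutant RNA these were well above background on 4, 3 and 1 of 8 arrays. All 12 engulfment and mother-cell genes rose, also adjusted over the list alone, with a camera adjusted p = 6.4e-09 (0.413 with an estimated correlation). Their median of 1.37 over the hours became 2.42 with Agilent's processed signals, 2.30 with the authors' values and 2.29 with scaling between arrays. Their median was 2.67 at 28 h, 2.30 at 30 h, 0.73 at 34 h and 0.17 at 36 h.

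Forespore genes rose in WT over sigG, 3 of 3 by both adjustments (camera adjusted p = 0.000486, and 0.201 with an estimated correlation), as did 3 of 5 genes of small acid-soluble spore proteins (camera adjusted p = 0.00233, and 0.413 with an estimated correlation). Sporulation regulators rose in 10 of 11 cases and fell in 1, by both adjustments (median 1.22, camera adjusted p = 2.48e-06, and 0.201 with an estimated correlation), with spoIIAA at 2.18 ± 0.21 (adjusted p = 2.96e-06) and sigE at 1.42 ± 0.49 (adjusted p = 5.97e-06). All 5 granulose genes rose by both adjustments (camera adjusted p = 0.000508, and 0.421 with an estimated correlation). Heat shock genes fell in 3 of 8 cases (4 over the list alone; median -0.89, camera adjusted p = 0.0284, and 0.661 with an estimated correlation), with dnaK at -1.40 ± 0.73 (adjusted p = 0.0024). The list's median was -0.16 at 28 h, -0.19 at 30 h, -1.69 at 34 h and -1.61 at 36 h. The calls of hsp18 and grpE were lost without 34 h and without 36 h. ATP synthase genes fell in 4 of 8 cases (7 over the list alone; median -0.80, camera adjusted p = 0.00736, and 0.633 with an estimated correlation). Of these calls those of atpC and atpD were lost with scaling and without any 1 of the 4 hours, and 2 to 5 genes fell over the alternatives. Solventogenesis genes fell in 4 of 7 cases and rose in 1, also over the list alone (camera adjusted p = 0.217). Their median was 0.48 at 28 h, -0.34 at 30 h, -1.41 at 34 h and -1.66 at 36 h. Over the alternatives 0 to 4 of them fell and 0 to 1 rose. ack fell 2.00-fold (adjusted p = 1.07e-05), within an acid formation list with 2 of 5 genes higher and 2 lower by both adjustments. Both higher calls were lost with median centring, and 0 to 2 genes of the list rose over the alternatives. The unlisted tags CAC3318 (5.30 ± 0.71, adjusted p = 5.35e-16) and CAC3585 (-2.80 ± 0.35, adjusted p = 4.42e-07) moved most. In sigG mutant RNA CAC3318 was well above background on 1 of 8 arrays. limma called 1070 genes, 642 higher and 428 lower, 299 at least 2-fold. The count was 706 without the 34 h sample, 677 with median centring, 1632 with scaling between arrays, 1904 with slide as a random block, and 440 without samples that had a dim array, here those of 30 and 36 h.

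**Figure D2:**
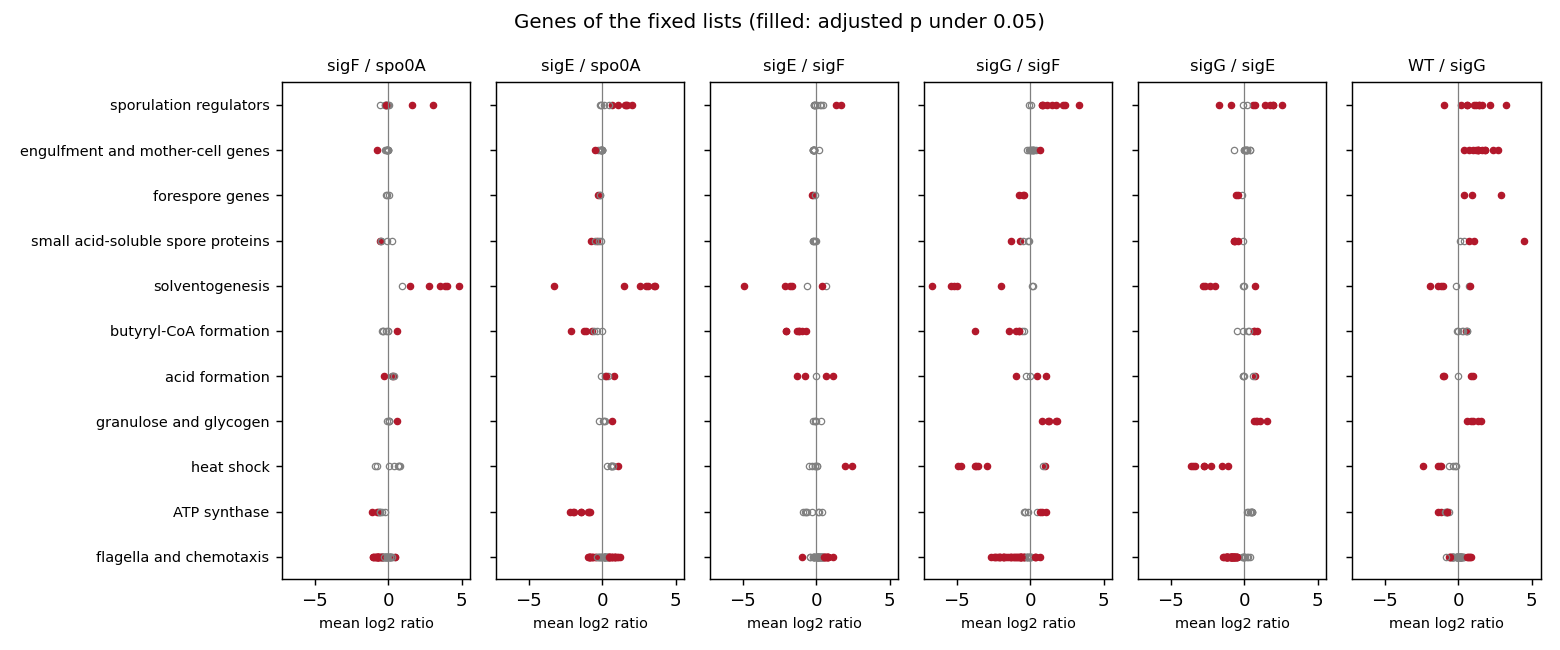
Mean log2 ratio (horizontal axis) of each gene in 11 fixed lists (vertical axis) for the 6 comparisons, 1 point per gene, filled where limma's adjusted p was under 0.05. All 12 engulfment and mother-cell genes are filled and above 0 in WT over sigG, and all 8 heat shock genes are filled and below 0 in sigG over sigE.

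**Figure D3:**
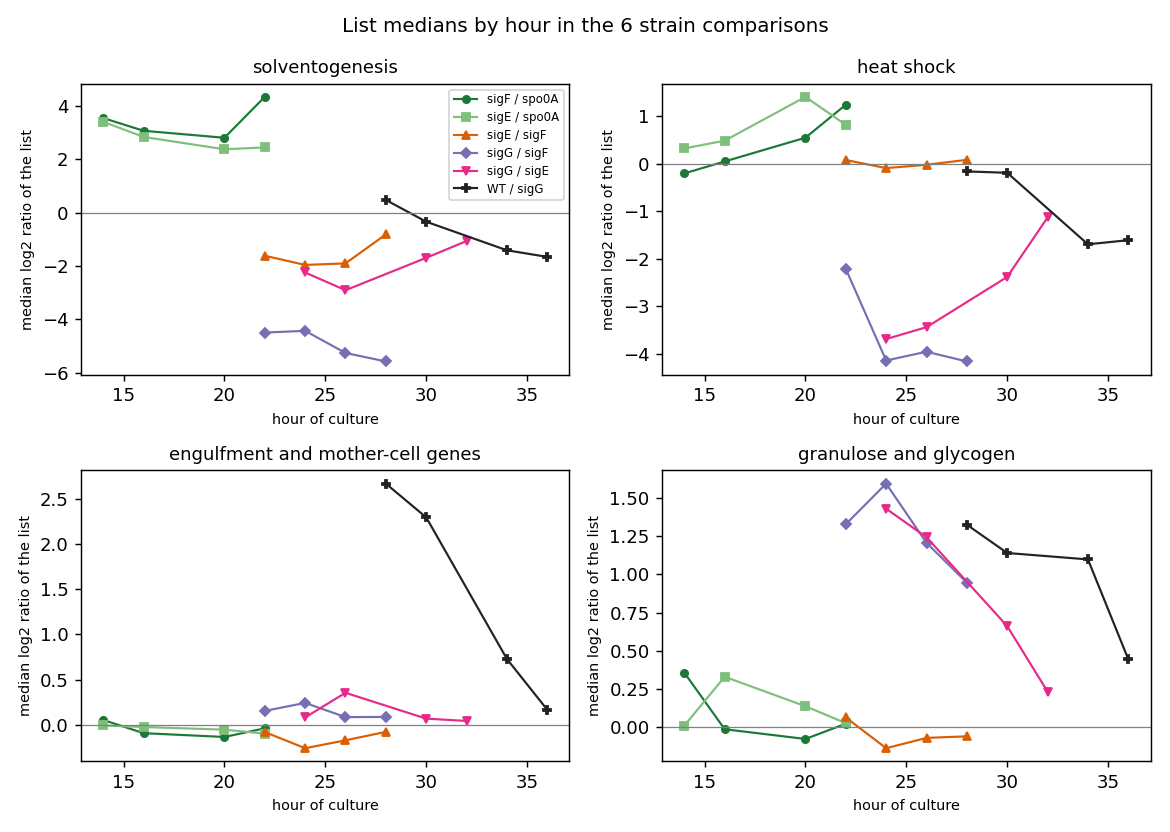
Median log2 ratio of a list (vertical axis) by hour of culture (horizontal axis), 1 line per comparison, for 4 lists. The heat shock median lies between -4.16 and -2.21 in sigG over sigF, and the engulfment and mother-cell median in WT over sigG runs from 2.67 at 28 h to 0.17 at 36 h.

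List median, mean and test differed in sign for sporulation regulators in sigF over spo0A, for acid formation and heat shock in sigE over sigF, for pSOL1 in sigG over sigF, for acid formation in sigG over sigE, and for acid formation, flagella and pSOL1 in WT over sigG. The same held for engulfment and heat shock genes in the difference over spo0A and for pSOL1 in the difference over sigF. Where hours allowed, direct log2 ratios were set against the sum of both other sides of a triangle of strains, across 3809 genes: the slope was 1.03 (r = 0.971) for spo0A, sigF and sigE at 22 h, and 1.02 (r = 0.935) at 24 h and 0.938 (r = 0.909) at 26 h for sigF, sigE and sigG.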

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

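Tests chosen only after the result was seen were the heat shock medians by dye orientation and 60-mer, in sigG over sigE and in WT over sigG, the spoIIGA and sigG values for the sigE transcript, and the median of the other pSOL1 genes.

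Heat shock genes were lower in the sigG mutant than in the samples labelled sigE mutant and, but for the chaperonin genes groEL and groES, than in the sigF mutant, where groEL was higher (1.04, adjusted p = 0.0143). That call of groEL was lost with scaling between arrays (0.69, adjusted p = 0.201) and without 22 h (0.76, adjusted p = 0.107). Faulty probes or dye bias as the cause of the list's shift would bring its median near 0 in 1 dye orientation or 60-mer, but over all 8 members the median nearest to 0 was -2.59, while by single members 6 of 8, all but groEL and groES, were at least 2-fold lower in each. An unusual sigF mutant culture alone would leave sigG over sigE near 0, where the list's median was -2.72. An unusually low sigG mutant culture would put WT over sigG above 0, if wild type is a fair reference. The median there was -0.89, with -0.16 at 28 h, -0.19 at 30 h, -1.69 at 34 h and -1.61 at 36 h. Wild type also differed from the mutants in antibiotic and in heat-shocking of its colonies, so a low sigG mutant culture is not excluded. A stress response in strains blocked before SigG may be involved, but so may a difference in growth stage or a single culture per strain; neither was tested, and no biological explanation was tested.

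The sigE transcript was higher in the samples labelled sigE mutant. A faulty probe is argued against by the lower of both 60-mers in both comparisons, 1.11. Transcription of the whole operon from its own promoter would raise spoIIGA, the first gene, along with sigE, but spoIIGA was at least 2.36-fold higher in the sigG mutant than in the samples labelled sigE mutant, where sigE was lower (-0.92 in sigG over sigE). That sigE was lower rests on this direct comparison. By the route over the sigF mutant sigE did not differ between these strains (0.12, limma adjusted p = 0.742). Transcription that starts at the insertion and runs on into sigE and the neighbouring tag sigG, which also stood higher (1.71 in sigE over sigF), could account for this and was not tested. Exchanged labels of the sigE and sigG mutants cannot be told apart from it by the sigG value of -1.72 in sigG over sigE, because the place of the 60-mers relative to the insertions is not known.

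Of 7 solventogenesis genes 5 were lower in the sigG mutant than in the sigF mutant and 2 did not pass. The 5 lower genes are those that lie on pSOL1, and the other 2, bdhA and bdhB, do not. Loss of the plasmid would also give this split. Loss of pSOL1, which carries ctfA, ctfB, adhE1, adhE2 and adc, would lower the plasmid's other genes alike. The median of the other 172 pSOL1 genes was 0.13 (quartiles -0.45 and 0.56), and 29 of them were at least 2-fold lower. By the test 74 of them rose and 47 fell, and loss would not give the rises. Genes dim in both strains would stand near 0 with or without the plasmid, and these were not counted. A shift in the course of the fermentation between the strains, or a single culture per strain, may account for the difference; neither was tested.

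A single hour stood apart from the other 3 by Dixon's criterion in 6 of 159 groups of 4 hours, where chance gives about 1 in 20 (7.95). In sigF over spo0A, sigG was -0.30 at 20 h (others -0.19 to -0.18, near background) and glgP (CAC1664) 1.74 at 14 h (others 0.14 to 0.22). CAC0474 was -0.65 at 16 h in sigE over spo0A (others -0.28 to -0.27) and -1.04 at 28 h in sigG over sigF (others -0.57 to -0.52). dnaK was -2.40 at 22 h in sigG over sigF (others -4.42 to -4.08), and spo0A was 0.43 at 26 h in sigG over sigE (others 0.82 to 0.90).

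Both comparisons against spo0A differed from each other in 662 genes. Chance cannot be excluded for this count, since 2 of the 35 splits of the 8 samples gave as many genes. The other split, with 769, exchanges the samples of 14 h between both comparisons. Genes named for this difference were groEL (1.95), sigF (1.02), abrB (-1.33), thlB (-2.71) and adhE2 (-4.25), and sigE (2.19), sigG (1.84) and buk2 (CAC1660, 0.52), whose fitted values are no measured sizes, being near background in sigF over spo0A. Of these sigF lost its call without subtraction of background, with scaling between arrays and without any 1 of the 4 hours, sigG and adhE2 with scaling (adjusted p = 0.123 and 0.0824), and buk2 with median centring (0.39, adjusted p = 0.252). groEL lost its call with scaling (1.78, adjusted p = 0.0554) and without 16 or 20 h, and abrB with scaling, without 16 h and with median centring (-0.67, adjusted p = 0.284). Both comparisons against sigF differed in 1552 genes. Only 1 of the 35 splits, the real one, gave as many, and the highest other gave 159, so the difference was steady over the hours. The samples are hours, and a chance difference between single cultures would give the same. The splits therefore do not exclude chance. Named there were spoIIAB (2.83), sigF (2.10), glgC (1.85), sigG (-0.88), grpE (-3.28), ctfA (-3.54), dnaK (-3.67), clpC (-4.58) and hsp18 (-4.98), and spoIIAA (2.18) and spoIIGA (1.90), whose fitted values are no measured sizes, being near background in sigF mutant RNA. The sigF transcript was also near background in sigF mutant RNA in sigG over sigF, so its value is uncertain in size. With scaling between arrays ctfA was -0.15 (adjusted p = 0.946), hsp18 -2.27 (adjusted p = 0.12), spoIIAA 1.33 (adjusted p = 0.0591) and glgC 1.13 (adjusted p = 0.0722). sigG lost its call with scaling (-1.32, adjusted p = 0.203), with Agilent's processed signals (-0.56, adjusted p = 0.333) and without 24, 26 or 28 h.

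For each single comparison 1 of 8 sign patterns of the 4 hours, the real one, gave as many genes, and 8 patterns are too few for a share under 0.05. The real and the highest other counts were 1427 and 119 for sigF over spo0A, 1832 and 842 for sigE over spo0A, 912 and 0 for sigE over sigF, 2413 and 6 for sigG over sigF, 1761 and 981 for sigG over sigE, and 1070 and 96 for WT over sigG.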

How the results depend on the processing

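Alternatives chosen only after the data were seen were the median over all spots, a dye term per scan run, leaving out the slide that 2 comparisons share, and leaving out samples with a dim array; the first 3 kept every count of genes within 1.5 times, and the cause of other shifts was not tested unless stated. Of 181 values of named genes 164 passed the test, 70 of these lost their call in at least 1 alternative, most often with scaling between arrays (45), and 3 changed direction, all with median centring: in sigE over spo0A spoVD became 0.025 and spoIVB 0.0096, and in sigG over sigF ptb (CAC3076) became 0.28. Under no background subtraction 172 of the 181 kept direction and side of the threshold, under Agilent's processed signals 171, under median centring 153, under scaling 135 and under the authors' values 176. The mean over 60-mers was not run, being the same as the median over at most 2. Signal near background limits values of dim genes. Folds given here may be too small for some lists and too large for others. The granulose median in sigG over sigF was 1.25, against 2.85 with Agilent's processed signals. The solventogenesis median there was -4.98, against -3.97. Of 29 list medians past the test 20 moved by more than 1.5 times in at least 1 of 5 ways of processing, 12 of them with median centring and 10 with scaling, and 3 turned, a count made after the data were seen.

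Counts fell by construction at a 2-fold threshold: 435 for sigF over spo0A, 625 for sigE over spo0A, 251 for sigE over sigF, 784 for sigG over sigF, 355 for sigG over sigE, 299 for WT over sigG, 287 for the difference over spo0A and 551 for that over sigF. Fitted alone, with fewer samples for the spread, they were 810 for sigF over spo0A, 1182 for sigE over spo0A, 637 for sigG over sigE and 111 for the difference over spo0A. With slide as a random block, whose correlation was -0.134 and which counts dye-swapped arrays as separate samples, they were 2254, 2197 (sigE over sigF), 2653 (sigG over sigE), 1904 (WT over sigG), 1825 and 2576 (both differences). Median centring gave 516 for sigE over sigF and 677 for WT over sigG, and scaling 1632 for WT over sigG and 815 for the difference over sigF. Without dim-array samples, and so with fewer samples, 155 remained in number for sigE over sigF, 440 for WT over sigG and 735 for the difference over sigF. With an estimated correlation 0 list calls passed. Genes higher over spo0A in both strains numbered 274 with each comparison fitted alone and 253 in a split of hours, and those higher over sigF in both 171 and 137 in the splits.

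Leaving out 1 hour gave 1124 to 1346 genes for sigF over spo0A, 1362 to 1909 for sigE over spo0A, 397 (without 24 h) to 796 for sigE over sigF, 2093 to 2268 for sigG over sigF, 977 (without 26 h) to 1848 for sigG over sigE and 706 (without 34 h) to 1028 for WT over sigG. It gave 209 (without 16 h), 281 (without 20 h), 368 (without 22 h) and 1161 (without 14 h) for the difference over spo0A, and 967 (without 26 h) to 1303 for that over sigF.

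With hour as a replicate block the difference over spo0A had 17 genes and that over sigF 1824. Residuals of samples of the same hour correlated with -0.0188 overall in the spo0A pair (-0.194 to 0.297 by hour) and 0.249 overall in the sigF pair (-0.102 at 26 h, and 0.177 to 0.407 at the others). Since not every hour was above 0.1 in either pair, the hours were not shown to pair the samples.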

Other observations

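The tests and genes here that were chosen only after their values were seen are the profiles of CAC0079 and CAC0078 and of their neighbours, and the use of hours other than 30 h for engulfment and mother-cell genes.

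CAC0079 and CAC0078, tags without a function here, differed widely between strains. CAC0079 stood at 8.86 in sigF over spo0A and 8.36 in sigG over sigE, at -6.91 in sigE over sigF, and at 0.09 (adjusted p = 0.808) in sigE over spo0A. It stood at 1.22 in sigG over sigF and -1.41 in WT over sigG. CAC0079 was well above background on 3 of 8 arrays in spo0A mutant RNA in sigF over spo0A. The same held for RNA labelled sigE mutant in sigE over sigF and in sigG over sigE, so its largest values are uncertain in size. CAC0078 stood at 6.22, 5.21, -2.57, -0.16 (adjusted p = 0.792), 2.37 and -0.996 (adjusted p = 0.113) in the same comparisons. The next tag, CAC0080, stood at 1.01, -0.03, 0.04, 0.96, 0.19 and -0.29, and CAC0081 at 0.95, -0.09, 0.40, 1.13, 0.87 and -0.37. The explanation of this profile was not tested.

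Engulfment and mother-cell genes rose in WT over sigG and did not pass in sigG over sigE. If the later hours of WT over sigG accounted for this, both comparisons would be alike at 30 h, the hour they share. There the list's medians were 2.30 and 0.07, a difference of 2.23, with 12 of 12 members higher in WT over sigG. This rests on 1 sample each, and the 30 h sample of WT over sigG has a dim array (17.5% and 10.1% of gene spots well above background). The median in WT over sigG was also 2.67 at 28 h and fell to 0.73 and 0.17 at 34 and 36 h, against 0.08, 0.35 and 0.04 at 24, 26 and 32 h in sigG over sigE, which argues against the later hours. Mother-cell genes may depend on a step that the sigG mutant lacks, or the sigG mutant culture may lag behind wild type at these hours; antibiotic and heat-shocked colonies also separate the strains, and none of these was tested.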
